A study of Mus musculus with 6 samples.

How the data were processed

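RNA was measured in 6 libraries of cells labelled as mouse aortic vascular smooth muscle cells, 3 labelled as Nt5e knock-out and 3 as wild type. Per the labels' protocols, cells grown at 10% serum were held at 0.5% serum for 48 h, and libraries were made from 1 ug of total RNA with a stranded kit that selects polyadenylated RNA. The deposited table gives, for each of 25683 genes and each library, whole-number read counts made by the authors, namely exon reads, unique exon reads, exon junction reads, intron reads and all reads of the gene, with gene coordinates. Its column of expression values equals the total exon reads in every entry. An RPKM value by the authors (deposited beside the counts, reads scaled by exon length and sequencing depth) was not used in any test. The genome build is GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool and the handling of strand are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain to that extent. Of the 25640 genes found in GENCODE release M21, 99.18% had the same coordinates there. Exon length was absent for 3742 genes, which held no reads, and 9384 genes had 0 reads in every library.

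Depth ranged from 19919095 to 23669252 exon reads per library, of which 97.4% to 97.6% were unique, and the 10 most abundant genes took 6.10% to 6.44% of reads. The mitochondrial share was 2.97%, 4.27% and 4.31% in knock-out libraries 1, 2 and 3 and 3.64%, 3.90% and 3.53% in wild-type libraries 4, 5 and 6. Genotypes were taken from the labels. Library titles also carry a stem, a number after the letter p and a last number, whose meaning the labels do not give, and these served only in alternatives.

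Total exon reads were tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr with a minimum count of 10 and TMM scaling, by the quasi-likelihood F test with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM are counts scaled by the TMM-adjusted library size, and log2 CPM used a prior count of 2. For genes with 0 reads in a genotype, the fold is a bound with 3 reads over that group, and for 1 to 3 reads a ratio with an exact 95% interval is given. Gene lists, 37 of them, were fixed from textbook knowledge before the data were examined. Those with at least 5 tested members, 35 lists, were tested with camera (limma 3.58.1, preset correlation of 0.01) and adjusted over the lists. The lists include adenosine, cAMP, TGF-beta and BMP components, TGF-beta response, elastic fibres, collagens, proteoglycans, matrix proteases, contractile genes, vasoactive receptors, mineralisation, cell cycle, p53 and senescence, interferon, cytokines, cholesterol, hypoxia, ATF4, NRF2, Wnt with Notch and hedgehog, growth factors and Hox genes. Further lists hold markers of endothelium, fibroblasts, leukocytes, pericytes, adipocytes, skeletal and cardiac muscle, Schwann cells and epithelium with mesothelium, and, as checks, mitochondrial, immediate early, histone, sex-linked and ribosomal protein genes and neighbours of Nt5e.

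Genes named in the text were drawn from a rule fixed before the data were examined. It takes Nt5e, Eln, Tgfb2, Acta2, Tagln, Myh11, Cnn1 and the 4 adenosine receptors, the 12 largest rises and 12 largest falls among called genes whose genotypes do not overlap at a mean of at least 50 reads, and up to 2 rises and 2 falls per biological list. For marker and check lists it takes up to 2 members of highest mean and up to 2 of smallest p. Krt14 among the genes left with summed pairs, Des, Myocd, Cald1 and genes of the comparison of knock-out library 1, were named after their values were seen.

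Alternatives fixed beforehand were DESeq2 size factors, total counts, no filter, a filter of 50 reads in 3 libraries, libraries of one title stem summed, the stem as a random effect in limma-voom, either title number as a covariate, DESeq2 1.42.0, limma-voom, leaving out each library, and, for lists, camera with an estimated correlation and fry. Those added after seeing the data were unique exon reads, the libraries with titles ending in 2, knock-out libraries 2 and 3 summed, both nearly identical pairs summed, and rescaling by chromosome. On simulated counts for the 12660 tested genes, over 3 runs with 200 changed genes each, edgeR called 27.3% of 2-fold and 78% of 4-fold changes, and 5.11% of its calls were false. camera called 15 of 15 raised lists and 0 of 45 others. Genes and libraries were simulated as independent. These rates therefore do not cover lists of correlated genes or nearly identical libraries, both present in the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.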

Results

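Poly(A)-selected RNA was sequenced from 6 libraries of cultured mouse aortic cells, labelled by the submitters as a primary line of vascular smooth muscle cells, the contractile cells of the vessel wall. There were 3 libraries from Nt5e knock-out cells (libraries 1 to 3) and 3 from wild-type cells (libraries 4 to 6). Nt5e encodes CD73, the cell-surface enzyme that converts AMP to adenosine. All cells had been kept at 0.5% serum for 48 h after growth at 10% serum, and the series title places the comparison in the context of adenosine signalling, TGF-beta 2, elastin and cellular contraction. Exon reads per library numbered 22743666, 22508062 and 19919095 in the knock-out and 21654804, 23669252 and 20813477 in the wild type. Nothing in the labels says that the libraries come from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

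The targeted gene was measured first, as a check of the genotype labels. Nt5e (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092, plus strand, GRCm38) had 615, 688 and 486 exon reads in wild-type libraries 4, 5 and 6 and 22, 1 and 2 in knock-out libraries 1, 2 and 3. Its normalised level was 26.1 ± 3.11 CPM in the wild type and 0.369 ± 0.506 CPM in the knock-out (mean ± SD, n = 3 each), a log2 fold change of -6.06 ± 0.82 (SE; adjusted p = 0.00577, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Relative to the wild-type mean, knock-out libraries 1, 2 and 3 stood at 3.65%, 0.181% and 0.408%. Reads spanning exon junctions of Nt5e numbered 10 in library 1 and 0 in libraries 2 and 3, against 184, 179 and 160 in the wild type. Intron reads of the gene did not follow its exon reads, with 37 over the 3 knock-out libraries and 34 over the 3 wild-type libraries. With knock-out libraries 2 and 3 summed and wild-type libraries 4 and 6 summed, pairs that were nearly identical, the log2 fold change of Nt5e was -5.81 and its call was lost (edgeR adjusted p = 0.133). Nt5e moved to -8.34 (log2 fold change) without knock-out library 1.

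Over 12660 tested genes, 3524 (27.8%) differed between knock-out and wild type, 1788 higher and 1736 lower in the knock-out (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 1427 of them, 565 higher and 862 lower. All 3 knock-out values lay above or below all 3 wild-type values for 49.7% of the tested genes. Chance gives 10% if the 6 libraries are independent samples, and more if the nearly identical libraries are not. When only total counts were used for scaling, 40.1% of the called genes were higher instead of 50.7%. The count of 3524 depended on single libraries: it was 8486 without knock-out library 1, which leaves the nearly identical libraries 2 and 3, 1606 without 2 and 1642 without 3, and 1120, 1671 and 1386 without wild-type library 4, 5 and 6. With each nearly identical pair summed to 1 sample, leaving 2 samples per genotype, 17 genes passed, 3 higher and 14 lower, among them Tspan8, Upk3b and Krt14.

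Libraries of one genotype were not equally alike. Principal component 1 of the 500 most variable genes held 84% of the variance and parted the genotypes, with scores of -18.8, -62.8 and -64.7 for knock-out libraries 1, 2 and 3 and 47, 52.3 and 46.9 for wild-type libraries 4, 5 and 6. Component 2 (12%) set knock-out library 1, at -42.3, apart from the other libraries. The biological coefficient of variation was 3.65% between knock-out libraries 2 and 3 and 3.49% between wild-type libraries 4 and 6, although the libraries of each pair carry different title stems. Libraries with the same stem differed more, by 44.1% for knock-out libraries 1 and 2 and 15.7% for wild-type libraries 5 and 6. Knock-out library 1 differed about as much from wild-type libraries 4, 5 and 6, by 43.9%, 47.7% and 43.4%, as from knock-out libraries 2 and 3, by 44.1% and 44.6%. The chi-square per degree of freedom was 3.33 and 3.35 for the nearly identical pairs, above counting noise. That does not show separate cultures, so n = 3 counts libraries, not cultures. The 4 libraries whose titles end in 2 are these nearly identical pairs, so the 9286 genes that differed by genotype among them were tested on the spread within such pairs, and titles ending in 1 have 1 library per genotype and gave no value.

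**Figure D1:**
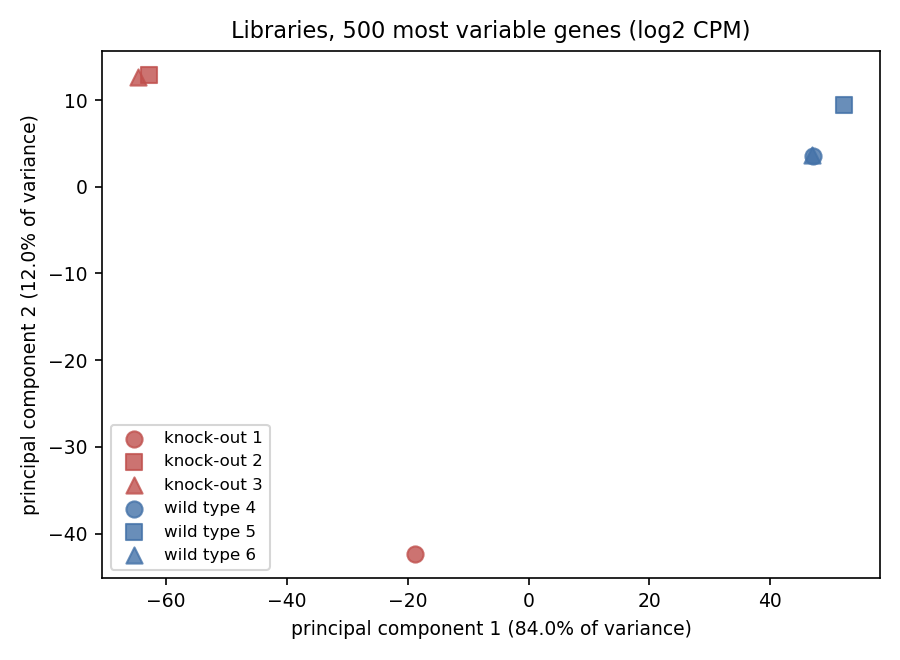
Scores of the 6 libraries on principal components 1 and 2 of the 500 most variable genes, with knock-out libraries in red and wild-type libraries in blue. Knock-out library 1 lies at -18.8 on component 1, between knock-out libraries 2 and 3 and the wild type, and alone at -42.3 on component 2.

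Elastin rose in the knock-out cells. Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323, minus strand, GRCm38), the gene of the core protein of elastic fibres, stood at 4.02 ± 1.31 CPM in the wild type and at 13.3, 20.03 and 21.1 CPM in knock-out libraries 1, 2 and 3, a log2 fold change of 2.17 ± 0.32 (SE, n = 3 each; edgeR adjusted p = 0.00704). Among genes of elastic fibres and their assembly, 10 of the 25 tested members rose and 2 fell, against 12 and 3 adjusted over the list alone and 16 and 6 without knock-out library 1. Loxl2, a cross-linking enzyme, rose (2.40 ± 0.62, 0.0358), while Fbln1 (-4.24 ± 0.28, 8.02e-04) and Emilin2 (-1.0 ± 0.14, 0.00646) fell, where parentheses give the log2 fold change ± SE and the edgeR adjusted p. The list as a whole did not pass (camera adjusted p = 0.0771), but it passed as a rise with total counts (0.0289), with the stricter filter (0.0435), with the stem as a random effect (0.0481) and without wild-type library 6 (0.0497). It did not pass with stems summed (0.0850), and the random effect, which called 9654 of 12660 genes, had a fitted correlation of -0.91 within stems. With an estimated correlation the adjusted p in the other passing settings was at least 0.416. Its median log2 ratio to the wild type was 0.55, 0.41 and 0.51 in knock-out libraries 1, 2 and 3. Tgfb2, the ligand named in the series title, was at 73 ± 3.51 CPM in the wild type and 81.9 ± 4.03 CPM in the knock-out and did not pass (0.17 ± 0.07, 0.147), but passed with the stem as a random effect (0.13, 0.00439) and with the nearly identical pairs alone, as 4 libraries (0.15, 0.0248). With the nearly identical pairs summed, the log2 fold change of Eln was 2.21 (edgeR adjusted p = 0.134) and that of Tgfb2 0.17 (0.478). The call of Loxl2 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.130).

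Components of the TGF-beta and BMP pathways moved both ways: 9 of the 44 tested members rose and 3 fell, against 14 and 5 adjusted over the list alone and 22 and 13 without knock-out library 1. Bmp4 (2.0 ± 0.19, 0.00218) and Smad6 (1.72 ± 0.20, 0.00359), an inhibitory Smad, rose. Grem1, a secreted BMP antagonist, fell from 1094 ± 469.8 to 98.6 ± 17.1 CPM (-3.47 ± 0.34, 0.00241), and Inhbb fell (-2.84 ± 0.58, 0.0184). Among genes known to respond to TGF-beta, 11 of the 33 tested members rose and 2 fell, against 13 and 3 adjusted over the list alone and 19 and 10 without knock-out library 1. Tgfbi (3.45 ± 0.99, 0.0485) and Snai2 (3.25 ± 0.88, 0.0413) rose, but Tgfbi stood at 10.9, 163 and 204 CPM in knock-out libraries 1, 2 and 3 against 11.6 ± 1.31 CPM in the wild type, so its rise lay in libraries 2 and 3. Snai2 stood at 6.32, 67.4 and 72.2 CPM in those libraries against 5.12 ± 1.08 CPM, so its rise lay mostly in libraries 2 and 3 too. Angptl4 (-2.12 ± 0.35, 0.00995) and Cdkn2b (-0.95 ± 0.25, 0.0386) fell. Neither list passed as a whole (camera adjusted p = 0.112 and 0.112). Pathway components passed as a rise with the stem as a random effect (0.0453) but not with stems summed (0.10). Responsive genes passed as a rise with total counts (0.0289) and with stems summed (0.0315), though not there with an estimated correlation (adjusted p at least 0.438), nor with the stem as a random effect (0.0699), which had a fitted correlation of -0.91 within stems. The median of the responsive genes was 0.01, 0.63 and 0.83 in knock-out libraries 1, 2 and 3. Inhbb moved to -3.65 (log2 fold change) without knock-out library 1. The calls of Inhbb, Tgfbi, Snai2 and Cdkn2b ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0656, 0.161, 0.147 and 0.116).

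Acta2, smooth muscle actin, stood at 73.8, 546 and 525 CPM in knock-out libraries 1, 2 and 3 against 74.1 ± 24.9 CPM in the wild type and did not pass (2.36 ± 0.75, 0.0633). It passed as a rise with stems summed (2.49, 0.0130), with the stem as a random effect (1.54, 0.00145), with the last title number as covariate (1.97, 0.0378), in DESeq2 (2.36, 0.00128), without knock-out library 1 (2.85, 1.15e-04) and with the nearly identical pairs alone, as 4 libraries (2.64, 9.54e-12), where parentheses give the log2 fold change and adjusted p. Tagln, at 17 ± 2.17 CPM in the wild type and 21.4 ± 3.91 CPM in the knock-out, did not pass (0.33 ± 0.18, 0.202) but passed with the stem as a random effect (0.26, 0.00390), without knock-out library 1 (0.47, 0.0104) and with the nearly identical pairs alone, as 4 libraries (0.38, 0.00127), and Cnn1 fell from 2.07 ± 0.995 to 0.369 ± 0.206 CPM (-2.45 ± 0.55, 0.0246). With the nearly identical pairs summed, Acta2 (2.16, 0.335), Tagln (0.31, 0.547) and Cnn1 (-2.15, 0.219) did not pass (log2 fold change and edgeR adjusted p). The random effect called 9654 of 12660 genes, and the 4 libraries called 9286 of 12721. Without knock-out library 1, 8486 of 12817 passed. A pass in these settings was thus the outcome for most genes. Myh11, smooth muscle myosin heavy chain, was below the count filter, with 5, 54 and 67 reads in knock-out libraries 1, 2 and 3 and 7 over the wild-type libraries. Without knock-out library 1 it entered the test with a log2 fold change of 4.81 (edgeR adjusted p = 1.25e-04). Des and Myocd, a structural gene and a regulator of smooth muscle, chosen after their values were seen, had 2 and 2 reads over the wild-type and 4 and 5 over the knock-out libraries. Among contractile genes, 7 of the 28 tested members rose and 1 fell, against 8 and 1 adjusted over the list alone and 17 and 4 without knock-out library 1. Vcl, a focal adhesion protein, rose (1.02 ± 0.10, 0.00225). The list did not pass (camera adjusted p = 0.0771), but it passed as a rise with total counts (0.0289), with the stricter filter (0.0287), with stems summed (0.0224), without knock-out library 1 (0.00536), without wild-type library 6 (0.0497) and with the nearly identical pairs alone, as 4 libraries (0.00435). With an estimated correlation the adjusted p in these settings was at least 0.725, and the list did not pass with the stem as a random effect (0.176). Its median was 0.12, 0.60 and 0.57 in knock-out libraries 1, 2 and 3. The call of Cnn1 ended without knock-out library 2 or 3 or wild-type library 4 or 6 (edgeR adjusted p up to 0.0879).

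**Figure D2:**
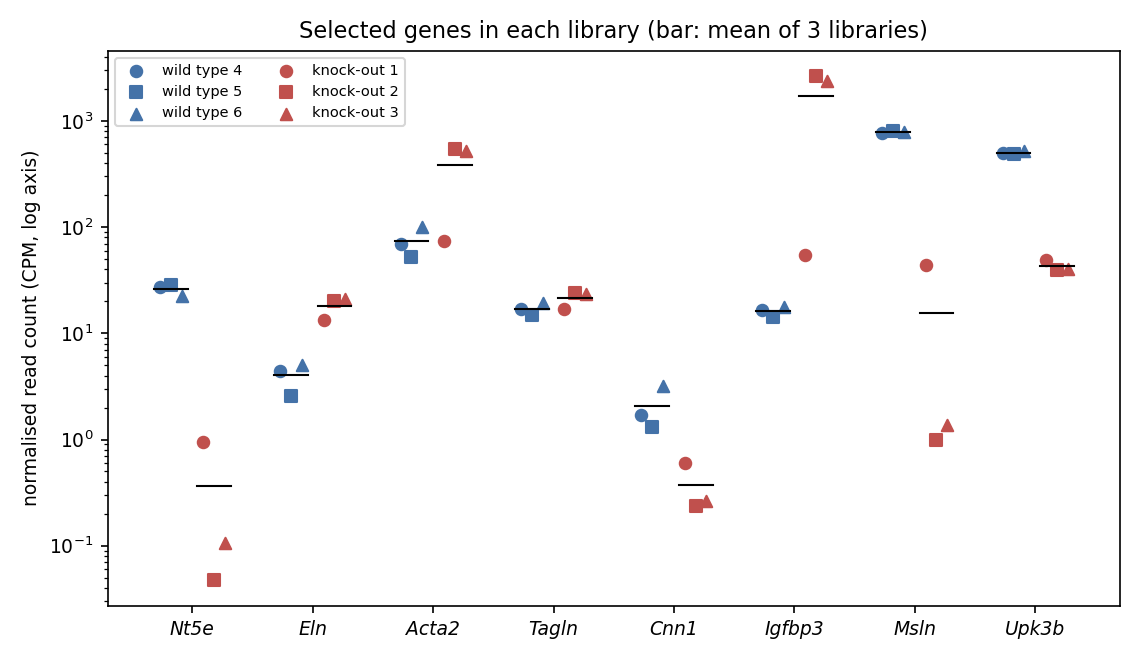
Normalised read counts (CPM, log axis) of 8 genes in each of the 3 wild-type (blue) and 3 knock-out (red) libraries, with a bar at the mean of the 3. Nt5e lies at or below 0.952 CPM in each knock-out library, Eln lies above every wild-type library in each of them, and for Acta2 and Igfbp3 knock-out library 1, at 73.8 and 54.6 CPM, lies far below knock-out libraries 2 and 3.

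Among receptors for vasoactive agents and ion channels, 5 of the 38 tested members rose and 11 fell, against 9 and 13 adjusted over the list alone and 13 and 17 without knock-out library 1 (camera adjusted p = 0.360). The alpha-1 adrenoceptor genes Adra1b (2.29 ± 0.34, 0.00716) and Adra1d (1.07 ± 0.14, 0.00559) rose. Kcnma1, the large-conductance calcium-activated potassium channel, had 1707 reads over the wild-type libraries and 0 over the knock-out libraries, at least 526-fold lower. The bound sets the knock-out group at 3 reads and, like all intervals given for reads, covers counting error only. The list median was -0.20, -0.28 and -0.42 in knock-out libraries 1, 2 and 3.

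Genes listed for adenosine metabolism and its receptors changed in both directions, as 5 of the 27 tested members rose and 8 fell, against 5 and 8 adjusted over the list alone and 5 and 9 without knock-out library 1 (camera adjusted p = 0.654). The falls include Nt5e itself, the targeted gene, whose fall was fixed by the design. Slc29a1, the equilibrative nucleoside transporter ENT1, rose from 28.9 ± 1.31 to 157 ± 20.4 CPM (2.44 ± 0.12, 4.14e-04), and Adk, adenosine kinase, rose (0.75 ± 0.10, 0.00594). Adk lies on chromosome 14, whose genes had a median log2 fold change 0.38 above that of all tested genes. Adora2a, an adenosine receptor that raises cAMP, fell from 40.3 ± 2.70 to 9.11 ± 1.36 CPM (-2.15 ± 0.14, 7.49e-04), and Dpp4 fell (-3.71 ± 0.24, 7.62e-04). Adora2b stood at 2.29, 13.6 and 12.9 CPM in knock-out libraries 1, 2 and 3 against 16.3 ± 7.37 in the wild type and did not pass (-0.77 ± 0.68, 0.429). It passed with the stem as a random effect (-1.47, 8.02e-04), which called 9654 of 12660 genes at a fitted correlation of -0.91 within stems. Its log2 fold change was -0.31 without knock-out library 1 (edgeR adjusted p = 0.463) and 0.10 with titles ending in 2 (0.538). Adora1 had 3 reads over the knock-out and 12 over the wild-type libraries, lower by a ratio of 3.69 with a 95% counting interval of 0.997 to 20.4, so no difference was detectable at this depth. Adora3 had 0 and 1, too few for a ratio. Among genes of the cAMP and CREB response, 9 of the 33 tested members rose and 3 fell, against 9 and 6 adjusted over the list alone and 13 and 10 without knock-out library 1 (camera adjusted p = 0.586). Atf3 (1.40 ± 0.33, 0.0267) and Pde3b (2.86 ± 0.77, 0.0412) rose, Pde3b to 7.79, 43.5 and 47 CPM in libraries 1, 2 and 3, and Gem (-2.67 ± 0.75, 0.0453) and Nfil3 (-0.59 ± 0.16, 0.0385) fell. The medians were 0.05, -0.05 and -0.09 for the adenosine genes and 0.13, 0.32 and 0.28 for the cAMP genes in knock-out libraries 1, 2 and 3. Gem moved to -1.61 (log2 fold change) without wild-type library 5. The call of Atf3 ended without wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.103). The calls of Pde3b, Gem and Nfil3 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.129, 0.133 and 0.124).

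Matrix genes held some of the largest changes. Of the collagens, 4 of 30 rose and 6 fell (4 and 6 adjusted over the list alone, 13 and 11 without knock-out library 1). Col15a1 (6.36 ± 1.64, 0.0361) and Col6a3 (5.96 ± 1.33, 0.0236) rose, mostly in knock-out libraries 2 and 3. Col15a1 stood at 1.86, 113 and 133 CPM in knock-out libraries 1, 2 and 3 against 0.988 ± 0.795 in the wild type. Col6a3 stood at 10.6, 302 and 367 CPM in those libraries against 3.61 ± 1.23, and the list median there was -0.53, 0.30 and 0.38. Col6a5 (-6.04 ± 1.14, 0.0147) and Col27a1 (-2.57 ± 0.65, 0.0336) fell. Of the proteoglycans and matricellular genes, 11 of 44 rose and 3 fell (12 and 4 adjusted over the list alone, 22 and 11 without knock-out library 1), with a median of -0.00, 0.36 and 0.45 in knock-out libraries 1, 2 and 3. Lama2, a laminin chain, rose from 0.617 ± 0.109 to 36.5, 265 and 274 CPM in knock-out libraries 1, 2 and 3 (8.27 ± 1.0, 0.00424). Spp1, osteopontin, fell from 333, 2315 and 298 CPM in wild-type libraries 4, 5 and 6 to 3.44 ± 3.07 CPM (-8.14 ± 1.34, 0.00985), and Has1, a hyaluronan synthase, fell (-5.38 ± 0.37, 8.16e-04). Of the matrix proteases and their inhibitors, 7 of 44 rose and 8 fell (9 and 8 adjusted over the list alone, 18 and 16 without knock-out library 1), with Mmp16 (4.45 ± 0.41, 0.00193) higher and Mmp13, at 11.1, 48.5 and 11.5 CPM in wild-type libraries 4, 5 and 6, lower (-4.09 ± 0.73, 0.0126) and a median of -0.19, 0.29 and 0.27. No list passed as a whole (camera adjusted p = 0.808, 0.337 and 0.822 in this order), and for the collagens the test pointed to a fall while the median, 0.08, and the mean, 0.38, lay above 0. Spp1 moved to -9.18 (log2 fold change) without knock-out library 1, Col6a5 to -7.91 without knock-out library 3, and Col15a1 to 7.11, Col6a5 to -5.19, Col27a1 to -1.69, Spp1 to -6.50 and Mmp13 to -3.02 without wild-type library 5. The calls of Col15a1, Col6a3 and Col27a1 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.128, 0.102 and 0.113). The call of Col6a5 ended without knock-out library 2 or wild-type library 5 or 6 (edgeR adjusted p up to 0.0610). The call of Mmp13 ended without knock-out library 3 (edgeR adjusted p = 0.0528).

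Mineralisation and osteochondrogenic genes were divided, as 4 of 24 rose and 4 fell (4 and 4 adjusted over the list alone, 10 and 7 without knock-out library 1), with a median of 0.24, a mean of -0.25 and a test in the direction of a rise that did not pass (camera adjusted p = 0.80). Phex rose (5.03 ± 1.26, 0.0329) to 0.606, 13.9 and 20.6 CPM in knock-out libraries 1, 2 and 3, and Bmp6 fell (-0.78 ± 0.22, 0.0476). Of the growth factors and their receptors, 17 of 46 rose and 5 fell (19 and 8 adjusted over the list alone, 21 and 18 without knock-out library 1) (camera adjusted p = 0.337). Igfbp3, a binding protein of insulin-like growth factors, stood at 16.2 ± 1.79 CPM in the wild type and at 54.6, 2643 and 2389 CPM in knock-out libraries 1, 2 and 3 (6.71 ± 1.43, 0.0210), while Igfbp5 fell (-2.78 ± 0.71, 0.0344) and Hgf fell (-0.97 ± 0.23, 0.0284). Of the Wnt, Notch and hedgehog genes, 12 of 37 rose and 11 fell (14 and 12 adjusted over the list alone, 16 and 15 without knock-out library 1), with a median of 0.32, a mean of -0.07 and a test in the direction of a rise that did not pass (camera adjusted p = 0.735). The receptor Notch1 (3.87 ± 0.82, 0.0202) and its ligand Jag1 (2.84 ± 0.55, 0.0156) rose, and the Wnt inhibitor Sfrp1 (-4.23 ± 0.36, 0.00156) and the Wnt target Axin2 (-3.93 ± 0.22, 5.24e-04) fell. Library medians of these 3 groups were -0.13, 0.28 and 0.25 for mineralisation, 0.12, 0.20 and 0.16 for growth factors and 0.07, 0.08 and 0.13 for Wnt, Notch and hedgehog genes in knock-out libraries 1, 2 and 3. Igfbp5 moved to -4.02 (log2 fold change) without knock-out library 1, and Phex to 4.34 without knock-out library 3. The calls of Phex, Bmp6, Igfbp3, Igfbp5, Hgf, Notch1 and Jag1 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.120, 0.166, 0.0939, 0.101, 0.0974, 0.0832 and 0.0688).

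Cell cycle genes were lower in the knock-out. Of this list, 2 of the 54 tested members rose and 22 fell, against 2 and 28 adjusted over the list alone and 5 and 40 without knock-out library 1, and the list passed in the direction of a fall (camera adjusted p = 1.72e-05), but not with a correlation taken from the data (adjusted p = 0.790 with an estimated correlation). Rrm2 (-1.75 ± 0.33, 0.0150) and Tk1 (-1.70 ± 0.36, 0.0204), enzymes of nucleotide supply for DNA synthesis, fell, while Ccnd2 rose from 277 ± 14.4 to 566 ± 17.5 CPM (1.03 ± 0.08, 0.00118) and Mcm6 rose (0.62 ± 0.13, 0.0180). The list median was -0.53, -1.16 and -1.21 in knock-out libraries 1, 2 and 3, where that of epithelial and mesothelial markers was -3.49, -5.43 and -5.75. Wild-type library 5 stood at 0.27, above libraries 4 and 6 at -0.17 and -0.09. Genes of the p53 response and senescence were higher, as 11 of the 32 tested members rose and 2 fell, against 12 and 2 adjusted over the list alone and 17 and 9 without knock-out library 1 (camera adjusted p = 0.0170, and adjusted p = 0.418 with an estimated correlation). Sesn1 rose (1.34 ± 0.27, 0.0171). Without knock-out library 1 the p53 list no longer passed (camera adjusted p = 0.0640), with library medians of 0.55, 0.36 and 0.42. Of 40 histone genes fixed as a list, 6 were tested, H1f0 among them, with 0 calls in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2 (camera adjusted p = 0.690). With so few members measured in RNA selected for poly(A), this result does not bear on the fall of cell cycle genes. The call of Rrm2 ended without knock-out library 2 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0604). The calls of Tk1 and Sesn1 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0740 and 0.0701). The call of Mcm6 ended without knock-out library 2 or wild-type library 4 or 6 (edgeR adjusted p up to 0.0740).

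Of the cytokines and chemokines, 2 of the 33 tested members rose and 12 fell, against 2 and 13 adjusted over the list alone and 4 and 25 without knock-out library 1, and the list passed in the direction of a fall (camera adjusted p = 0.00289), though not with a correlation taken from the data (adjusted p = 0.740 with an estimated correlation). Saa3, an acute-phase protein, fell from 1290.1 ± 647 to 16.5 ± 4.0 CPM (-6.29 ± 0.48, 0.00120), and Lcn2 fell (-6.32 ± 0.94, 0.00738). Csf1 (0.59 ± 0.15, 0.0313) and Nfkb1 (0.48 ± 0.08, 0.0106) rose. The list median was -0.82, -1.45 and -1.65 in knock-out libraries 1, 2 and 3, where that of epithelial and mesothelial markers was -3.49, -5.43 and -5.75. Beside it, markers of macrophages and leukocytes gave 1 rise and 2 falls among 5 tested, the same adjusted over the list alone, with Cd14 (-2.45 ± 0.27, 0.00341) and Cd68 (-2.33 ± 0.34, 0.00704) lower and Lyz2 (2.57 ± 0.50, 0.0156) higher (camera adjusted p = 0.586). Their median was -0.83, -0.75 and -0.62 in knock-out libraries 1, 2 and 3. Lcn2 moved to -8.98 (log2 fold change) without knock-out library 1. The call of Csf1 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0978). The call of Nfkb1 ended without wild-type library 4 (edgeR adjusted p = 0.0565). The call of Lyz2 ended without knock-out library 2 or 3 or wild-type library 5 or 6 (edgeR adjusted p up to 0.0728).

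Stress and metabolic genes gave no list that passed. Of the NRF2 and antioxidant genes, 13 of 30 rose and 4 fell (13 and 5 adjusted over the list alone, 14 and 13 without knock-out library 1) (camera adjusted p = 0.337). Hmox1, haem oxygenase 1, rose from 68.1 ± 17.3 to 413 ± 187 CPM (2.60 ± 0.38, 0.00717) and Slc7a11, the cystine transporter, rose (2.71 ± 0.53, 0.0159), while Gsta4 (-2.93 ± 0.41, 0.00635) and Aldh1a1 (-2.06 ± 0.23, 0.00327) fell. Of the genes of the ATF4 and unfolded protein responses, 4 of 33 rose and 5 fell (5 and 5 adjusted over the list alone, 16 and 10 without knock-out library 1), with Atf5 (1.02 ± 0.18, 0.0115) higher and Chac1 (-1.21 ± 0.20, 0.0107) lower (camera adjusted p = 0.654). Of the hypoxia and glycolysis genes, 5 of 34 rose and 6 fell (5 and 7 adjusted over the list alone, 13 and 11 without knock-out library 1), with Hk1 (0.92 ± 0.20, 0.0219) higher, and Hif1a (-1.57 ± 0.17, 0.00306) and Egln3 (-2.30 ± 0.39, 0.0104) lower (camera adjusted p = 0.822). Of the cholesterol synthesis and uptake genes, 0 of 26 rose and 2 fell (0 and 1 adjusted over the list alone, 1 and 9 without knock-out library 1), among them Acat2 (-0.90 ± 0.25, 0.0439) (camera adjusted p = 0.223, and 0.0365 without wild-type library 6). In the wild type, library 5 stood apart for cholesterol genes, with a median of 0.39 against -0.14 and -0.23 in libraries 4 and 6. In knock-out libraries 1, 2 and 3 the medians were 0.28, 0.11 and 0.05 for NRF2 genes, 0.02, 0.21 and 0.17 for ATF4 genes, -0.29, 0.23 and -0.04 for hypoxia genes and -0.24, -0.17 and -0.24 for cholesterol genes. The call of Slc7a11 ended without knock-out library 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0735). The call of Atf5 ended without wild-type library 4 or 6 (edgeR adjusted p up to 0.0617). The calls of Hk1 and Acat2 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0920 and 0.134).

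**Figure D3:**
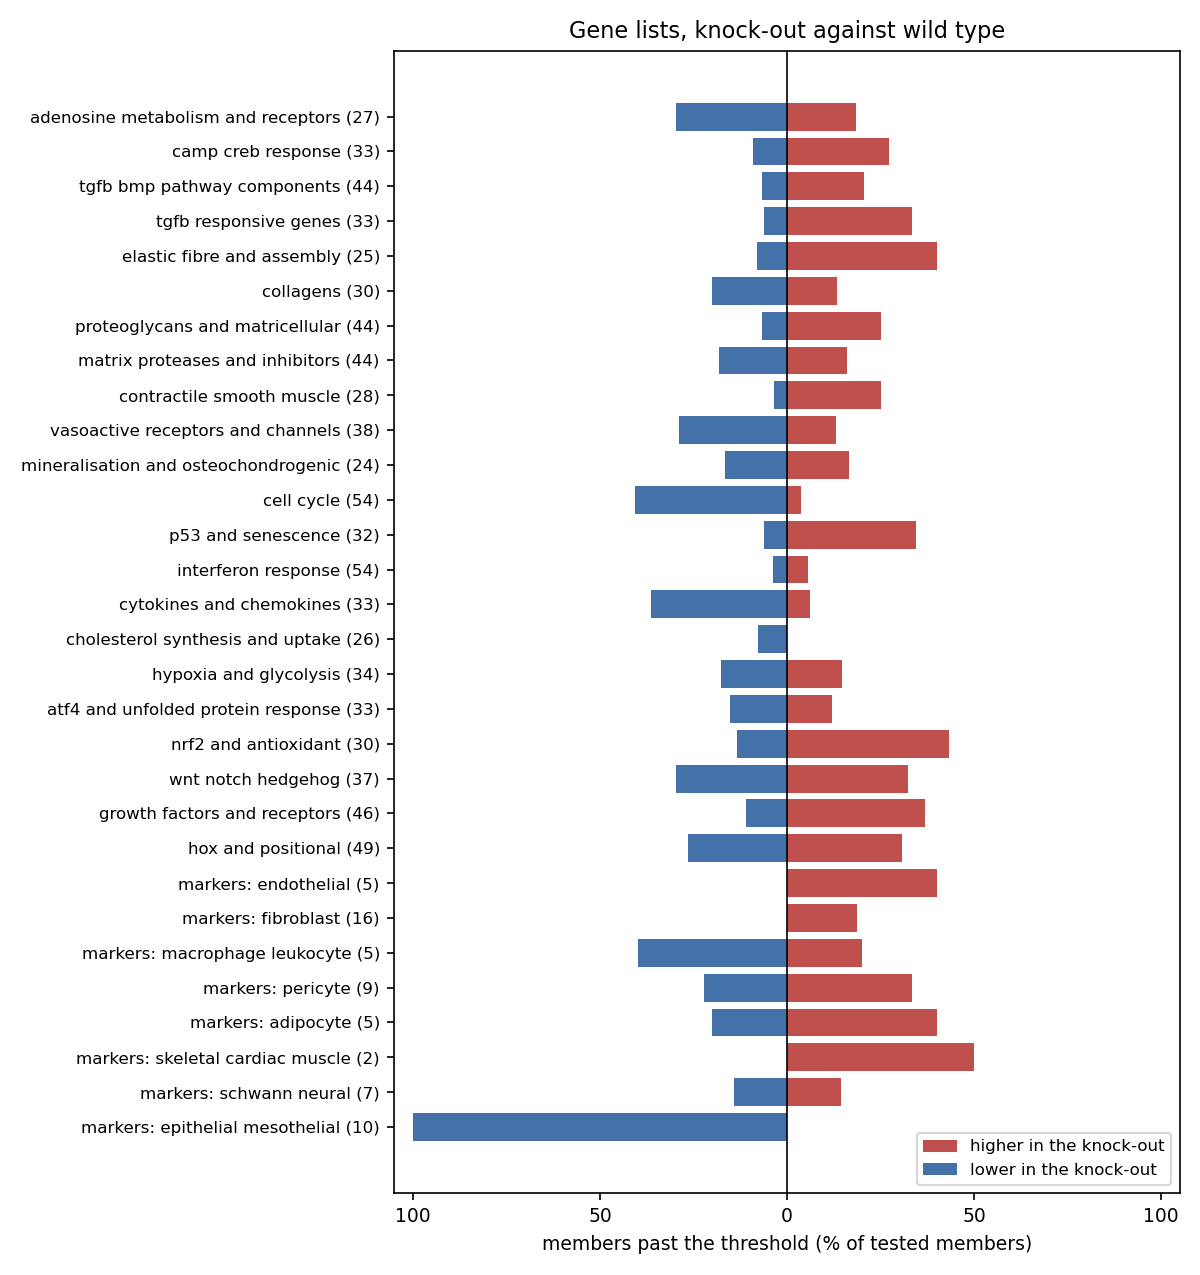
Share of the tested members of gene lists (number tested in parentheses) that rose (red, to the right) or fell (blue, to the left) in the knock-out at an edgeR adjusted p under 0.05. All 10 tested epithelial and mesothelial markers and 22 of 54 cell cycle genes were lower in the knock-out.

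Markers of epithelial and mesothelial cells fell together. All 10 tested members were lower in the knock-out, also when adjusted over the list alone and without knock-out library 1 (camera adjusted p = 1.47e-07), although the list did not pass with a correlation taken from the data (adjusted p = 0.227 with an estimated correlation). Their median log2 fold change was -5.14, or -4.48 with the 2 genes without a knock-out read set at their bound. In the wild type Msln, mesothelin, stood at 786 ± 18.7 CPM, Lrrn4 at 648 ± 41.3 CPM, Upk3b at 500.04 ± 15.9 CPM and Krt19 at 449.7 ± 11.3 CPM (mean ± SD, n = 3). Msln was thereby at percentile 99.3 of genes with a read, with Cald1 at 99.3, Acta2 at 80.9, Tagln at 49.7 and Myh11 at 15.5. In knock-out libraries 1, 2 and 3 Msln stood at 44, 0.990 and 1.38 CPM (-5.66 ± 1.57, 0.0437) and Upk3b at 48.4, 39.4 and 40.3 CPM (-3.55 ± 0.11, 1.25e-04). Muc16 had 7430 reads over the wild-type libraries and 0 over the knock-out libraries, at least 2287-fold lower. The list median was -3.49, -5.43 and -5.75 in knock-out libraries 1, 2 and 3. Msln moved to -9.38 (log2 fold change) without knock-out library 1. The call of Msln ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.114).

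Markers of other cell types did not move one way. For fibroblasts 3 of 16 rose and 0 fell (2 and 0 adjusted over the list alone, 7 and 4 without knock-out library 1), with Dcn at 2489 ± 169 CPM in the wild type and 2637 ± 269.8 CPM in the knock-out, not passing (0.08 ± 0.12, 0.618) except with the stem as a random effect (0.15, 0.00929), which called 9654 of 12660 genes, and with Scara5 (2.76 ± 0.23, 0.00144) and Pi16 (4.95 ± 0.72, 0.00702) higher. For endothelium 2 of 5 rose and 0 fell (2 and 0 adjusted over the list alone, 3 and 1 without knock-out library 1), Eng (1.49 ± 0.16, 0.00296) and Kdr (3.17 ± 0.59, 0.0138), Kdr from 0.532 ± 0.244 to 4.81 ± 2.43 CPM. For pericytes 3 of 9 rose and 2 fell (3 and 2 adjusted over the list alone, 3 and 3 without knock-out library 1), with Pdgfrb (2.02 ± 0.44, 0.0215) and Cspg4 (5.54 ± 0.60, 0.00316) higher and Steap4 (-3.41 ± 0.52, 0.00799) lower, a median of 0.10, a mean of -0.23 and a test pointing up. For adipocytes 2 of 5 rose and 1 fell (2 and 1 adjusted over the list alone, 2 and 3 without knock-out library 1), with Plin4 (1.74 ± 0.32, 0.0133) higher and Lpl (-4.90 ± 0.31, 7.49e-04) lower. For Schwann and neural cells 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone, 2 and 3 without knock-out library 1), with Cryab (0.60 ± 0.10, 0.00894) higher and Mbp (-3.26 ± 0.27, 0.00145) lower. Of the skeletal and cardiac muscle markers 2 were tested, too few for a list test, and Tnnt2 rose from 0.256 ± 0.220 to 21.2 ± 11.4 CPM (6.36 ± 0.79, 0.00453). None of these lists passed (camera adjusted p = 0.337, 0.30, 0.999, 0.778 and 0.735 for fibroblasts, endothelium, pericytes, adipocytes and Schwann cells). With fry, fibroblasts (adjusted p = 0.00119) and endothelium (0.00628) passed as rises and adipocytes (0.0335) as a fall. Only 5 of 16 listed endothelial and 5 of 14 listed adipocyte markers had enough reads to be tested. These passes therefore do not show a change of an endothelial or adipocyte programme. In knock-out libraries 1, 2 and 3 their medians were 0.24, 0.48 and 0.40 for fibroblasts, 0.45, 1.46 and 1.44 for endothelium, 0.26, -0.32 and -0.49 for pericytes, -0.20, -1.30 and -1.69 for adipocytes and 0.19, -0.35 and -0.96 for Schwann cells. Cspg4 moved to 4.81 (log2 fold change) and Steap4 to -4.19 without knock-out library 1, and Tnnt2 to 7.30 without wild-type library 6. The call of Kdr ended without wild-type library 5 or 6 (edgeR adjusted p up to 0.0674). The call of Pdgfrb ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0920). The call of Plin4 ended without wild-type library 4 or 6 (edgeR adjusted p up to 0.0577).

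Hox genes and other positional transcription factors, which record where along the body a mesenchymal cell arose, changed often and in both directions. Of these, 15 of the 49 tested members rose and 13 fell, against 16 and 16 adjusted over the list alone and 23 and 19 without knock-out library 1 (camera adjusted p = 0.822). Hand2 rose from 0.563 ± 0.185 to 27.7 ± 5.93 CPM (5.60 ± 0.31, 5.16e-04) and Hoxd8 rose (4.05 ± 0.86, 0.0207). Hoxb9 fell from 56 ± 10.2 to 2.94, 0.0943 and 0.0532 CPM in knock-out libraries 1, 2 and 3 (-5.70 ± 1.10, 0.0154), and Wt1, a transcription factor of mesothelium and epicardium, from 29.98 ± 3.92 to 3.64, 0.566 and 0.160 CPM (-4.33 ± 0.94, 0.0217). The list median was -0.39, 0.47 and 0.51 in knock-out libraries 1, 2 and 3. Hoxb9 moved to -9.45 (log2 fold change) and Wt1 to -6.31 without knock-out library 1, and Hoxd8 to 4.95 without wild-type library 4. The call of Hoxd8 ended without knock-out library 2 or 3 or wild-type library 6 (edgeR adjusted p up to 0.0893). The call of Hoxb9 ended without wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0662). The call of Wt1 ended without knock-out library 2 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0812).

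The largest single changes lay among genes nearly absent from one genotype. Muc16, Gkn2, Eya2, Kcnma1, Lhx8, Shisa3, Apba2, B3gnt7 and Cyp11a1 had 0 reads over the knock-out libraries, with bounds from at least 2287-fold lower for Muc16 and 2259-fold for Gkn2 to 136-fold for Cyp11a1. Tspan8 fell from 225 ± 20.6 to 0.0924 ± 0.0384 CPM (-11.12 ± 0.21, 3.78e-05), and Ptger3, with 1 knock-out read, was lower by a ratio of 1782 (95% counting interval 319.5 to 70439.9). In the other direction Ptprd and Cmklr1 had 0 wild-type reads and were at least 155-fold and 149-fold higher. Of the 413 knock-out reads of Cmklr1, 337 lay in library 1, without which its fitted log2 fold change moved from 10.07 to 8.37. Pik3r6 was higher by a ratio of 226 (62.3 to 1875), Mab21l1 by 132 (45 to 645) and Folh1 by 115 (39.2 to 563). Slitrk5 (7.24 ± 1.59, 0.0229), Aspn (6.45 ± 1.42, 0.0229), Capn6 (6.45 ± 1.52, 0.0277) and Arhgap6 (6.44 ± 0.74, 0.00369) also rose. Knock-out library 1 stood below libraries 2 and 3 for most of the rises, with Capn6 at 2.12, 92.4 and 112 CPM, and above them for Cmklr1, at 14.6, 1.79 and 2.02 CPM. Aspn moved to 5.86 (log2 fold change) without wild-type library 5, and Aspn to 8.25 without wild-type library 6. The calls of Cmklr1, Slitrk5, Aspn and Capn6 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0853, 0.0938, 0.102 and 0.113).

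Lists that track RNA handling, dissociation or the targeted locus gave no pass. Of the immediate early genes, 10 of 25 rose and 3 fell (12 and 7 adjusted over the list alone, 13 and 8 without knock-out library 1), with Klf4 (0.50 ± 0.09, 0.0121) and Klf6 (0.75 ± 0.13, 0.0109) higher and Klf2 (-2.17 ± 0.14, 7.49e-04) and Socs3 (-2.65 ± 0.19, 0.00103) lower (camera adjusted p = 0.337). Their median was 0.48, 0.53 and 0.37 in knock-out libraries 1, 2 and 3. Among genes close to Nt5e on chromosome 9, 1 of 23 rose and 6 fell (1 and 6 adjusted over the list alone, 3 and 14 without knock-out library 1), with Plscr1 (-0.85 ± 0.07, 0.00167) and Plod2 (-0.94 ± 0.20, 0.0216) lower and Tbx18 (0.87 ± 0.13, 0.00682) higher (camera adjusted p = 0.337), and library medians of 0.03, -0.54 and -0.50. Of the sex-linked list, 4 genes were tested, too few for a list test, and no member passed, against 2 at an unadjusted p under 0.05 and 2 in DESeq2. Without knock-out library 1, 4 of these 4, all Y-linked, were lower, with a median log2 fold change of -1.16 against -0.75 over all libraries. The Y-linked genes were present in every library. The call of Klf4 ended without knock-out library 2 or wild-type library 4 or 6 (edgeR adjusted p up to 0.0712). The call of Klf6 ended without wild-type library 4 or 6 (edgeR adjusted p up to 0.0626). The call of Plod2 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0872).

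Fold changes were not spread evenly over the chromosomes. Genes of chromosome 14 had a median log2 fold change 0.38 above that of all tested genes, outside the range of -0.10 to 0.08 over 1000 random gene sets of the same size, and 195 of its 427 tested genes rose while 27 fell. On chromosome 11 the shift was -0.20, with 80 rises and 274 falls among 1041 genes. Median shifts in knock-out libraries 1, 2 and 3 were 0.42, 0.39 and 0.36 on chromosome 14 and -0.19, -0.20 and -0.21 on chromosome 11. On chromosome 18 they were -0.16, 0.37 and 0.38, and on chromosome 9, which carries Nt5e, they were 0.09, -0.27 and -0.27. Eln lies on chromosome 5, where they were 0.09, -0.23 and -0.22. Of the genes named above, Adk, Bmp4, Loxl2, Scara5, Slitrk5 and Vcl, which rose, and Kcnma1, which fell, lie on chromosome 14. Their fold changes include any shift common to that chromosome. After each library was rescaled by chromosome, 2841 of the 3524 calls were kept in a total of 3522, and 21 of the original calls had a fold change of the other sign.

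**Figure D4:**
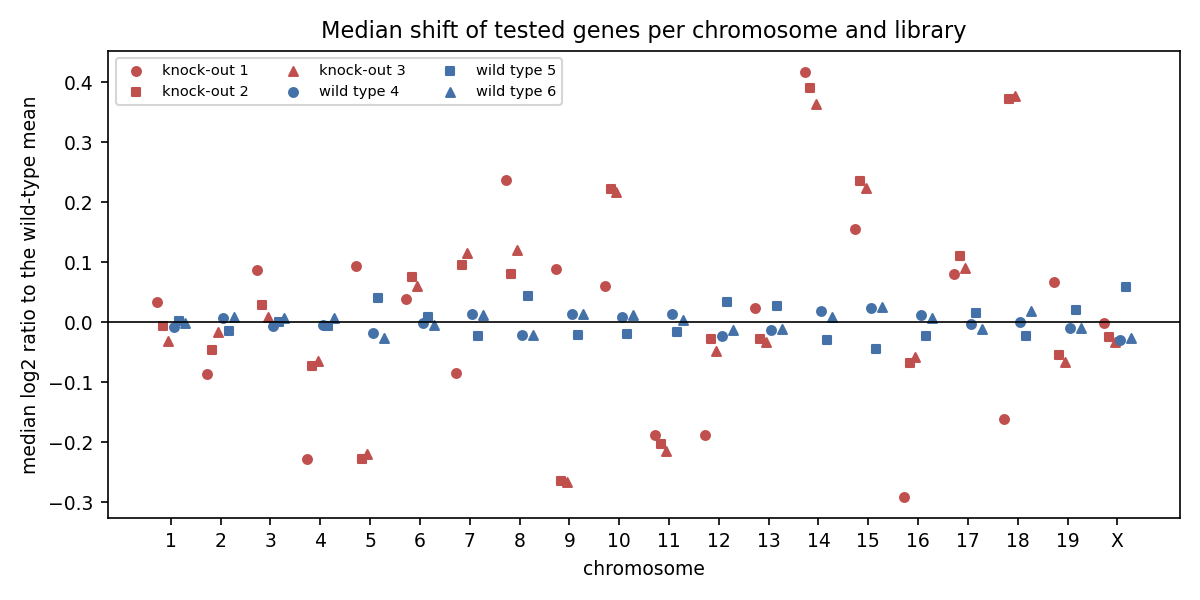
Median log2 ratio to the wild-type mean of the tested genes of each chromosome, per library, with knock-out libraries in red and wild-type libraries in blue. Chromosome 14 lies at 0.42, 0.39 and 0.36 in knock-out libraries 1, 2 and 3, while on chromosome 18 library 1, at -0.16, lies on the other side of 0 from libraries 2 and 3.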

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

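Intron reads, which the comparison by exon reads does not use, also parted the genotypes. Of 10653 genes tested on intron reads, 1280 passed, 531 higher and 749 lower in the knock-out (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the 2849 genes called on exon reads and tested on intron reads, 2530 (88.8%) had the same direction, and 896 were called on both. Across the 10257 genes tested on both, Pearson's r of the fold changes was 0.857 and Spearman's rank correlation 0.702, over genes that are not independent replicates and from the same libraries. This test was chosen after the contents of the table were seen, and no technical or biological explanation was tested for it.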

How the results depend on the processing

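Over 21 alternatives, no called gene was called in the opposite direction. Of the 129 named genes called other than Nt5e, 67 kept their call whichever library was left out, and 2 kept it with both nearly identical pairs summed. That setting, chosen after seeing the data like those on libraries 2 and 3, on titles ending in 2, on unique reads and on chromosomes, leaves 2 samples per genotype. It called 17 genes (3 higher, 14 lower), 17 by at least 2-fold, and Nt5e at -5.81 did not pass (edgeR adjusted p = 0.133, range over the alternatives 1.45e-12 to 0.133). With knock-out libraries 2 and 3 summed, 1631 genes passed (802 higher, 829 lower), 869 by at least 2-fold. With 1 library left out, the number of genes ran from 1120 to 8486, of higher genes from 513 to 4172, of lower genes from 607 to 4314, of genes changed at least 2-fold from 708 to 2757, and of lists from 4 to 7. With titles ending in 2, 9286 genes passed (4580 higher, 4706 lower), 2783 by at least 2-fold, with 7 lists, and mt-Atp6 turned from -0.06 to 0.20. The stem as a random effect gave 9654 genes (4762 higher, 4892 lower), with a fitted correlation of -0.91 within stems. Lists numbered 7 with total counts, 7 with stems summed, 15 with fry, and 0 in camera with an estimated correlation (2 at an unadjusted p under 0.05). The count of genes rose without knock-out library 1 and with titles ending in 2, and fell with any other library left out or nearly identical libraries summed, and the cause was not tested. In the remaining alternatives these counts stayed within 1.5 times. The epithelial and mesothelial, cell cycle and cytokine lists passed in every setting but the estimated correlation, and the p53 list also failed without knock-out library 1 (0.0640) and with titles ending in 2 (0.102, camera adjusted p). No paired analysis was possible because the genotypes share no replicate numbers, and their title numbers do not match libraries one to one. With the p number of the title as a covariate 3122 genes passed, 2928 of the 3524 calls were kept and 16 named genes lost theirs. With the last number these were 4510, 3480 and 6. A pseudocount setting was not run, since the values are counts. Depth limits genes with few reads, such as Adora1 and Adora3.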

Other observations

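Tests chosen only after the result was seen are those of the reads each gene needs, of the title stem, of Hox genes, of other splits for 2-fold genes and lists, of splits and alternatives with an estimated correlation and of marker medians without knock-out library 1, the test on intron reads, and the settings on unique exon reads, libraries 2 and 3 summed, pairs summed, titles ending in 2 and chromosomes.

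Interferon-response genes parted the knock-out libraries. Their median log2 ratio to the wild type was 0.95, -0.53 and -1.03 in knock-out libraries 1, 2 and 3 and 0.02, 0.02 and -0.01 in wild-type libraries 4, 5 and 6. Ifit3 stood at 298, 68.1 and 66.2 CPM in knock-out libraries 1, 2 and 3 against 19.99 ± 1.45 CPM in the wild type (2.85 ± 0.66, 0.0268), and Ifit2 at 145, 94.2 and 94.1 CPM against 39.6 ± 3.26 CPM (1.49 ± 0.20, 0.00534), where parentheses give the log2 fold change ± SE and the edgeR adjusted p. Gbp7 (-1.84 ± 0.48, 0.0358) and Psmb9 (-1.45 ± 0.26, 0.0129) fell. In all, 3 of the 54 tested members rose and 2 fell, against 2 and 1 adjusted over the list alone and 7 and 34 without knock-out library 1. The list did not pass with library 1 (camera adjusted p = 0.822, with a test pointing down while median, 0.23, and mean, 0.23, lay above 0) and passed in the direction of a fall without it (camera adjusted p = 0.00143), but not with an estimated correlation (adjusted p = 0.776 without library 1 and 0.993 over all libraries). Ifit3 moved to 1.74 (log2 fold change) and Gbp7 to -2.62 without knock-out library 1. The call of Ifit3 ended without wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.102). The call of Gbp7 ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.11). The call of Psmb9 ended without knock-out library 3 or wild-type library 4 or 6 (edgeR adjusted p up to 0.0669).

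Mitochondrially encoded and ribosomal protein genes also followed library 1. The 13 mitochondrial genes had medians of -0.29, 0.40 and 0.41 in knock-out libraries 1, 2 and 3, with 0 calls in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2 over all libraries (camera adjusted p = 0.547), and 9 rises without library 1 (camera adjusted p = 0.00492, and 0.00121 with the nearly identical pairs alone, as 4 libraries). With an estimated correlation the adjusted p was 0.776 and 0.777 there and 0.902 over all libraries. mt-Co1 stood at 8909.9, 12376 and 12458 CPM in knock-out libraries 1, 2 and 3 and 9377 ± 512 CPM in the wild type and did not pass (0.26 ± 0.16, 0.273), but passed with the stem as a random effect (0.18, 0.0184), without knock-out library 1 (0.40, 7.43e-04) and with the nearly identical pairs alone, as 4 libraries (0.43, 1.59e-07). Those settings called most tested genes, 9654 of 12660, 8486 of 12817 and 9286 of 12721 in this order. With the pairs summed mt-Co1 did not pass (0.17, edgeR adjusted p = 0.774). Of the ribosomal protein genes, 8 of 75 rose and 2 fell (0 and 0 adjusted over the list alone, 50 and 9 without knock-out library 1), with medians of -0.04, 0.26 and 0.30 (camera adjusted p = 0.0771). That list passed as a rise with stems summed (0.0487), with the last title number as covariate (0.0424), without knock-out library 1 (1.12e-04), with the nearly identical pairs alone, as 4 libraries (4.03e-04) and after rescaling by chromosome (0.0453), but with an estimated correlation the adjusted p in these settings was at least 0.776, and it did not pass with the stem as a random effect (0.337). Rpl37a (0.37 ± 0.07, 0.0162) was higher and Rps21 (-0.44 ± 0.07, 0.00873) lower. The call of Rpl37a ended without knock-out library 2 or 3 or wild-type library 4, 5 or 6 (edgeR adjusted p up to 0.0907). The call of Rps21 ended without wild-type library 4 (edgeR adjusted p = 0.0588).

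Knock-out library 1 stood apart from libraries 2 and 3 and held more Nt5e reads. Over 2757 genes that parted the wild type from libraries 2 and 3 by at least 2-fold, it lay at a median of 44.5% of the way to the wild type (95% bootstrap interval 40.9 to 47.8; quartiles 9.93 and 88.4, with 503 genes beyond the wild type and 389 beyond libraries 2 and 3), far above the 3.65% that its Nt5e reads would give if wild-type RNA were mixed in. Over 20 genes of the wild type nearly absent from libraries 2 and 3, its median share was 1.24%, but 7 had fewer reads than the lowest share its Nt5e reads allow (2.29%) would bring, among them Tspan8 with 3 reads where 109 are needed and Gkn2 with 0 where 49.4 are needed, which also argues against such a mixture. A shared batch of titles ending in 1 was tested by the deviations of knock-out library 1 and wild-type library 5. Their r of -0.0213 across genes argues against a large one. Library 1 differed from library 2 by 44.1%, and library 5 from library 6 by 15.7% (coefficient of variation). A batch that is small beside the deviation of library 1 could therefore stay unseen. It stays open that a title stem may not name the culture of library 2, since libraries 2 and 3, of different stems, differed by only 0.0828 times as much as libraries 1 and 2, of one stem, and that libraries of one genotype differ in biology, which was not tested.

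Chromosome-wide shifts set the knock-out libraries apart from the wild type. The largest among autosomes, 0.384 (log2) on chromosome 14, stayed at 0.368 after a trend on GC content and exon length was removed, and the smallest shift among its 3 equal parts by position was 0.370, so such a trend or a few regions do not account for it. A gain of chromosome 14 in part of the knock-out cells is a hypothesis found and tested on the same data. All values are relative to the wild type, so they cannot tell such a gain from a loss in the wild-type cells. All 3 knock-out libraries share that shift, whereas chromosome 18 is raised relative to the wild type in libraries 2 and 3 and not in 1. DNA copy number was not measured, and a co-ordinated change of transcription along chromosomes remains open. Rescaling by chromosome kept 2841 of the 3524 calls among 3522.

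The wild-type libraries carried abundant mesothelial transcripts, of which the knock-out libraries held far less. Myh11, Des and Myocd were at or below 2.11 CPM in both genotypes (means). In the wild type and knock-out, Tagln was at 17 and 21.4 CPM, Cnn1 at 2.07 and 0.369, and Acta2 at 74.1 and 381 (73.8 in knock-out library 1). Cald1 was at 843 and 1458 CPM, but Dcn, of the fibroblast list, was at 2489 and 2637. How far these cultures are smooth muscle cells, as labelled, stays open. A smaller share of smooth muscle cells in the wild type was tested only in the form where all other cell types take their place alike. Markers of every other type would then be lower in the knock-out, but the fibroblast median was 0.53 (log2, 95% bootstrap interval 0.05 to 1.58) and that of epithelial and mesothelial markers -5.14 (-7.17 to -3.55). Without knock-out library 1 these medians were 0.31 (-0.22 to 2.12) and -5.97 (-8.52 to -4.62). The fibroblast interval then includes 0, so the outcome depends on that library. Over all libraries the adipocyte and leukocyte medians, -0.94 and -0.36, lay below 0 with intervals that include it. If mesothelial cells alone took the place of smooth muscle cells, only their own markers would fall. These medians therefore cannot decide on a smaller share of smooth muscle cells. Cultures of another origin or cell make-up in each genotype stay open: Hox and positional genes were called more often than other tested genes (28 of 49, 57.1% against 27.7%, odds ratio 3.48, 95% interval 1.90 to 6.45, Fisher's exact p = 1.75e-05, two-sided). That test counts genes as independent, which genes measured in the same libraries are not, so its p-value and interval can overstate the evidence. The shares called were also high for Wnt, Notch and hedgehog (62.2%), NRF2 (56.7%) and immediate early genes (52%). No excess was tested for these lists, so a high share alone does not single out positional genes. An effect of Nt5e loss on cell identity cannot be told apart from another origin or make-up of the cultures, because the labels name no culture that both genotypes share.

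Of the 17 listed epithelial and mesothelial markers, 1 is also in another list, and 4 of the 10 tested stood above 1 CPM in every knock-out library.

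3 libraries against 3 allow 10 splits, too few for a share under 0.05. The genotype split called 3524 genes and 1 was the highest count among the other splits. By at least 2-fold it called 1427, and the highest other split called 1. For lists it called 4, and 9 of the 10 splits, the real one included, gave as many, with a highest other of 11, which points to a structure of the samples under the preset correlation. With an estimated correlation camera called 0 lists in every split, the real one included, with 2 in the real split and up to 4 in the others at an unadjusted p under 0.05, so the camera counts of lists rest on that preset and a structure of the samples is not shown without it. fry, which tests a list against no change and not against other genes, called 15 in the real split. Beside the 4 that camera called, these included elastic fibre, TGF-beta component, TGF-beta response, mineralisation, growth factor, fibroblast and endothelial lists as rises. Adenosine, vasoactive, leukocyte and adipocyte lists passed fry as falls. The adenosine list includes Nt5e itself, the targeted gene. Of the endothelial, leukocyte and adipocyte lists, 5 members each were tested, of 16, 20 and 14 listed.

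Within 10 Mb of Nt5e, 19 of 60 tested genes were called, an odds ratio of 1.20 against all other tested genes (95% interval 0.658 to 2.12, Fisher's exact p = 0.563, two-sided). The 4 Y-linked genes summed to at least 102 CPM in every library, and 4 were lower in the knock-out without library 1 (median log2 fold change -1.16).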
